A study of Caenorhabditis elegans with 3 samples.

How the data were processed

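Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where LIN-15B, a nuclear protein of the synMuv B class, lay on the genome of Caenorhabditis elegans. Per the labels, the animals were whole L1 larvae of mixed sex from strain OP184, which carries an inserted lin-15B transgene with an eGFP tag in an unc-119 mutant background. The labels give 1 group with 3 biological replicates and no control sample, so no comparison between groups was made. Replicates 1 and 2 came from a stock centre with fragments of 150 to 350 bp, per the labels. Replicate 3 came from the laboratory's own stock, and its labels name sonication with a microtip and a C-terminal GFP-FLAG tag. The antibody label names only the protein LIN-15B, while the sample descriptions name the eGFP fusion as the target, so whether the antibody bound the tag or the protein itself is not settled.

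The deposited files are peak lists, 1 per replicate and 1 series-wide list made from the alignments of all 3 replicates, each on the genome builds ce10 and ce11. Per the records deposited with them, each list was made against a control file and holds background as well as peaks, as input for a replicate comparison. The aligner and the peak caller are not given in the sources used here. The strength of each peak is a signal value that the authors' caller gave on its own scale, so it was used only to rank peaks within a list. The deposited q value of each peak was treated as a score, since the series-wide lists hold values slightly below 0. Every list has exactly 30000 peaks, so the length of a list is a limit set upstream and not a measurement. Peak lists give no read counts, so the depth of each replicate is unknown and no interval that rests on depth was computed. All coordinates are on ce11 and 1-based. The lists on ce10 were used for counts and strengths only, and nothing was converted between builds.

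Peaks of the series-wide list served as anchors, and each was matched to the strongest overlapping peak (1 bp or more) of each replicate. For each pair of replicates, the irreproducible discovery rate (IDR), a copula mixture model of the ranks, was fitted to the anchors matched in both, and an anchor passed at an IDR of 0.05 or less. Tied strengths were ranked in a seeded random order. Anchors that passed in all 3 pairs are called consistent peaks. A peak was assigned to every protein-coding gene with a transcript start for which the summit lay from 500 bp upstream to 200 bp downstream, in Ensembl release 115, and such a gene is called bound. The promoter share was tested against 100000 circular shifts of the summits along their chromosomes (permutation test, two-sided). Gene lists, the X chromosome and motifs were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 12 lists, over the 5 motifs and, as a separate family, over the 2080 6-mers. Base composition was compared in windows of 201 bp with a permutation test (100000 resamples, two-sided). Bound windows were centred on the summit. Windows of genes without a consistent peak were centred 156 bp upstream of the annotated gene start, the median position of bound summits. Errors over replicates come from each replicate's own 926 strongest peaks, as many as there were consistent peaks, and are given as mean ± SD.

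The 12 gene lists, the 5 motifs, the tests and most alternatives were fixed before the data were examined. The lists were P granule and germline RNA regulation, meiosis and synapsis, synMuv and DREAM, cell cycle and DNA replication, RNA interference, ribosomal proteins, proteasome, neuron, muscle, intestine, hypodermis and cuticle, and chemoreceptors. Of the listed names, 2 had no match in the annotation, rad-54 and rde-3, and were left out. The name rde-3 is an older one of mut-2, which was in the RNA interference list under that name. The named genes follow a rule fixed at the same time: genes at the promoters of the 10 consistent peaks with the best mean rank, up to 3 bound members of each list with the best mean rank, and a fixed set of genes reported as bound or not. Alternatives were another IDR threshold (0.01 or 0.1), matching by summits within 100 bp, anchors merged from the replicates, a pass in any pair, presence among the top 2000 peaks of every replicate, each replicate left out, other promoter sizes, the nearest transcript start only, a background of genes with any listed peak, shorter windows, a background matched on GC content in bins of 5 percentage points (Mantel-Haenszel odds ratio and test), and the ce10 lists.

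The IDR, gene list, promoter share, X chromosome, motif, 6-mer, GC content and CpG ratio tests were run on simulated data, and the other statistics were not. With ranks drawn from the fitted models, 5.03%, 4.93% and 5.09% of calls were false for replicates 1 and 2, 1 and 3, and 2 and 3, and 88.1%, 82.7% and 83.6% of reproducible anchors were recovered, among 6511, 7012 and 6127 simulated anchors. With no reproducible part, 0 anchors were called in 20 draws. Random sets of bound genes gave a false list call in 4% of 200 draws over 19973 genes, and randomly placed peaks gave a false promoter call in 4% of 100 draws of 900 peaks. For the list and X chromosome tests, bound genes were drawn independently. In the data a peak can mark several genes, and that dependence was not simulated. False calls came in 6.5% of 200 draws for the X chromosome, in 0% of 20 draws for motifs and 5% with GC matching, in 0% of 5 draws for 6-mers, and in 5% and 6% of 100 draws for GC content and the CpG ratio. Planted effects were recovered in 96% of draws for GC content and 100% for the other tests. The planted shift was 1 percentage point for GC content and 0.1 for the CpG ratio. For the gene lists a large excess was planted in the cell cycle list only. Recovery of weaker effects, or of effects in shorter lists, was not simulated. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.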

Results

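Peak lists of LIN-15B ChIP-seq in L1 larvae were compared among 3 biological replicates of 1 group. Each list held 30000 peaks, and the depth behind them is unknown. Peaks with a q score of 2 or more numbered 538 in replicate 1, 3083 in replicate 2 and 2206 in replicate 3. The usual peak width was 250, 224 and 300 bp in replicates 1, 2 and 3. The highest authors' strength was 284 in replicate 1, 252 in replicate 2 and 432 in replicate 3, on scales that are not comparable between lists.

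The first question was which binding sites the replicates share. Several of the strongest sites ranked alike in every replicate: the peak between rpl-20, a gene of the large ribosomal subunit, and Y17G9B.5 ranked 2 in all 3 replicates, and the peak between rps-12, a gene of the small subunit, and ska-3 ranked 3 in all 3. In all, 926 peaks passed the IDR threshold of 0.05 in all 3 pairs. Replicates 1 and 2 shared 1059 reproducible peaks of 6511 matched anchors, replicates 1 and 3 shared 1091 of 7012, and replicates 2 and 3 shared 1829 of 6127. Among the top 1000 peaks, 69.4% overlapped between replicates 1 and 2, 64.9% between 1 and 3 and 73.5% between 2 and 3, where shifted lists gave 0.502%, 0.588% and 0.601%. Among the top 5000, the overlaps were 27.8%, 27.1% and 41.1%, against 2.38%, 2.73% and 2.69% for shifted lists. The count of consistent peaks depends on replicate 1: without it, 1829 peaks passed. A small number of neighbouring anchors matched the same replicate peak, and with 1 anchor per replicate peak, an alternative chosen after seeing the data, 915 remained.

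The 10 consistent peaks with the best mean rank lay at promoters, 9 of them between protein-coding genes and 1 in an intron. The peak of rpl-20 (WBGene00004432) and Y17G9B.5 had its summit at position 4750067 of chromosome IV, 289 bp upstream of rpl-20 and 173 bp upstream of Y17G9B.5, and the 31 bp around it, from 4750052 to 4750082, read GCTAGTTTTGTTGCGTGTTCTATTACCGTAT. The peak of rps-12 (WBGene00004481) and ska-3 had its summit at 5679130 of chromosome III, 168 bp and 125 bp upstream of the respective starts, and the 31 bp from 5679115 to 5679145 read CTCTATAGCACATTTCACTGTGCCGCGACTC. The third site was upstream of cdc-48.1 (WBGene00007352), which encodes an AAA ATPase of protein degradation, at 10563570 of chromosome II, with a mean rank of 4.0 ± 2.65 (SD, n = 3). A peak at 13240683 of chromosome IV lay 361 bp upstream of lin-54 (WBGene00003037), which encodes a DNA-binding subunit of the DREAM complex, and 32 bp upstream of rpl-12, so the peak does not tell these genes apart. It had a mean rank of 4.33 ± 0.577 (SD, n = 3). The other top peaks lay upstream of iff-2, a translation factor gene, tasp-1, rpl-3, eelo-2, the pair hsr-9 and rps-19, and the pair C47E8.4 and hsp-90, a chaperone gene. The last of these, at 14685769 of chromosome V, was the intronic one. The peak of tasp-1 was the strongest of replicates 1 and 2 and ranked 15 in replicate 3.

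LIN-15B peaks lay mostly just upstream of genes. Of the 926 consistent peaks, 756 (81.6%) had the summit in a promoter, and they marked 1048 of 19973 protein-coding genes. Without replicate 1, 1839 genes were bound. Shifted peaks gave 16.4% ± 1.25 (SD over shifts), and the permutation p was 1e-05, the smallest that 100000 shifts can give. Among the 926 strongest peaks of each replicate, the promoter share was 81.1% ± 7.02 (SD, n = 3), from 74.0% in replicate 1 to 88.0% in replicate 3. The 926 weakest peaks of each list had a share of 17.5% ± 1.92 (SD, n = 3). Outside promoters, 128 consistent peaks were intergenic, 32 were in introns and 10 in exons, counting protein-coding genes only. The summits of the 756 promoter peaks lay a median of 156.5 bp upstream of the nearest transcript start, and 95.4% of them lay upstream, in a promoter that by definition reaches further upstream than downstream.

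**Figure D1:**
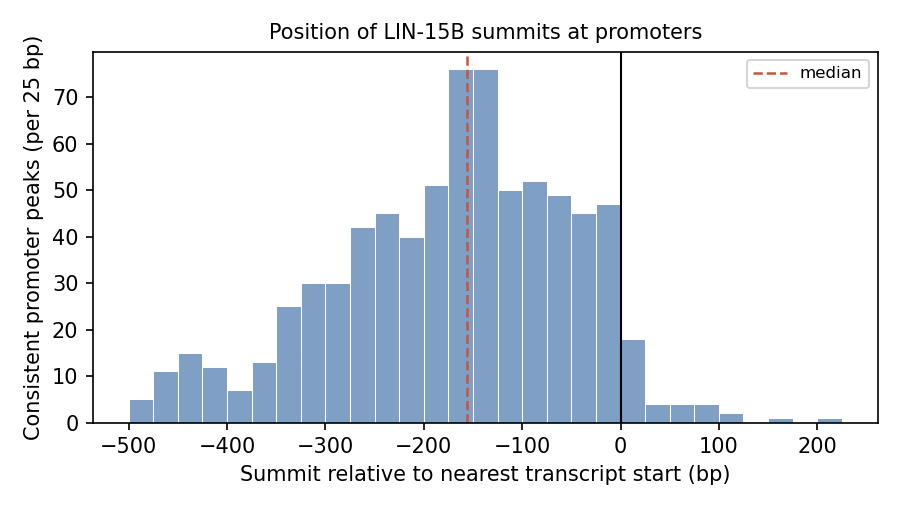
Histogram of the distance from the nearest transcript start (horizontal axis, bp, negative values upstream) for the 756 consistent peaks with the summit in a promoter (vertical axis, peaks per 25 bp). Distances are to the closest start of the assigned gene and can pass the promoter limit of 200 bp downstream. The summit 277 bp downstream is not drawn. The dashed line marks the median, 156.5 bp upstream, and 95.4% of summits lie left of the solid line at the start.

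The next question was which gene groups carried LIN-15B at their promoters. Ribosomal protein genes had the highest share with the promoter as defined: 52 of 78 were bound (66.7%), against 5.01% of other genes, led by rpl-20, rps-12 and rpl-12. Of the synMuv and DREAM genes, 8 of 22 were bound, led by lin-54, lin-9 and lin-38. Some genes of that list act in transcriptional repression with the retinoblastoma protein. The proteasome genes had 12 of 33 bound, led by rpt-2, rpn-3 and rpn-9, and the cell cycle and DNA replication genes 20 of 60, led by cdc-6, top-2 and cyb-1. In each replicate's own top peaks the shares were 68.8% ± 4.5 for ribosomal proteins, 39.4% ± 6.94 for synMuv and DREAM, 40.4% ± 7.63 for the proteasome and 33.9% ± 0.962 for the cell cycle (SD, n = 3). Fisher's exact test gave odds ratios of 37.9 (adjusted p = 9.09e-47), 10.4 (adjusted p = 2.22e-05), 10.4 (adjusted p = 1.56e-07) and 9.19 (adjusted p = 4.73e-11) for these 4 lists in that order. Many of these genes shared their peak with another promoter: 33 of the 52 ribosomal protein genes, 3 of the 8 synMuv and DREAM genes, 10 of the 12 proteasome genes and 13 of the 20 cell cycle genes, and another gene was nearer for 22, 2, 2 and 6 of them. All 3 named proteasome genes and all 3 named cell cycle genes are among those that shared, and acin-1, npp-3 and orc-5 lay nearer to the summit than cdc-6, top-2 and cyb-1. The top peaks of rpl-20, rps-12 and rpl-12 were shared as well, and Y17G9B.5 and ska-3 lay nearer than rpl-20 and rps-12. The peak of lin-54 is also that of rpl-12, which lay nearer, so it counts in both lists. With the nearest transcript start only, the cell cycle odds ratio was 7.90 and that of the proteasome 11.2. The order depends on the promoter size: with 250 bp upstream to 100 bp downstream, 13 of 78 ribosomal protein genes were bound (16.7%), fewer than synMuv and DREAM (31.8%), proteasome (30.3%) and cell cycle genes (25%). The ribosomal odds ratio was then 5.58 (Fisher's exact test, adjusted p = 8.87e-06), and it was 16.6 with the nearest transcript start only. The sizes also depend on replicate 1: without it, 66 of 78 ribosomal, 21 of 33 proteasome and 35 of 60 cell cycle genes were bound, with odds ratios of 56.2, 17.4 and 14.1, while synMuv and DREAM stayed at 8 of 22 with an odds ratio of 5.65.

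RNA interference genes had 6 of 39 bound, with mut-15, rde-4 and nrde-4 ahead, an odds ratio of 3.30 (Fisher's exact test, adjusted p = 0.0304). The share in the replicates was 16.2% ± 1.48 (SD, n = 3). In Fisher's exact test this call was lost when a peak counted for the nearest transcript start only (adjusted p = 0.310), with a promoter of 250 bp upstream to 100 bp downstream (adjusted p = 0.0938), and against genes with any listed promoter peak (adjusted p = 0.189). Both mut-15 and rde-4 shared their peak with another promoter.

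Neither germline list differed from other genes past the threshold, and lists of 40 and 39 genes are too short to show a lack of difference. Of the P granule and germline RNA regulation genes, 1 of 40 was bound, nos-3, which shared its peak with another promoter and had a mean rank of 866 ± 318 (SD, n = 3), and the odds ratio was 0.463 (Fisher's exact test, adjusted p = 0.723). Without replicate 2, 2 of 40 were bound and the odds ratio was 0.844. Of the meiosis and synapsis genes, 4 of 39 were bound (10.3%, against 5.24% of other genes), with brc-1, rad-51 and pch-2 ahead. The odds ratio was 2.07 (adjusted p = 0.219 by Fisher's exact test). At an IDR of 0.01 the odds ratio of the meiosis list was 0.562. Among the fixed genes, pgl-1, glh-1, deps-1, him-3 and him-8 had no listed promoter peak in any replicate. The promoters of pgl-3, glh-2 and htp-1 had listed peaks of low rank only, at 8247 in replicate 2 for pgl-3, 27186 and 18939 in replicates 1 and 3 for glh-2, and 12469 in replicate 3 for htp-1.

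None of the tissue genes on the fixed lists carried a consistent promoter peak in the main setting. None was bound among 50 neuron, 40 muscle, 40 intestine and 40 hypodermis and cuticle genes, and none of these lists passed Fisher's exact test alone (adjusted p = 0.194 for neuron and 0.297 for each of the others). The absence depends in part on replicate 1: without it, 3 muscle genes (7.5%, against 9.21% of other genes) and 2 neuron genes were bound. At an IDR of 0.1, 1 muscle and 1 neuron gene were bound. Outside the lists, 3 of 150 collagen genes of the col family were bound, col-38, col-71 and col-2 (2% against 5.27% of other genes). The cuticle collagen gene bli-6 was bound as well. The peaks of col-38 and bli-6 were shared with another promoter. Chemoreceptor genes, a large family expressed in sensory neurons, were bound below other genes, with 1 of 1166, sri-5, against 5.57% (odds ratio 0.0146, adjusted p = 4.93e-26 by Fisher's exact test). The peak of sri-5 was shared with another promoter. Without replicate 1, 3 chemoreceptor genes were bound (odds ratio 0.0238).

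**Figure D2:**
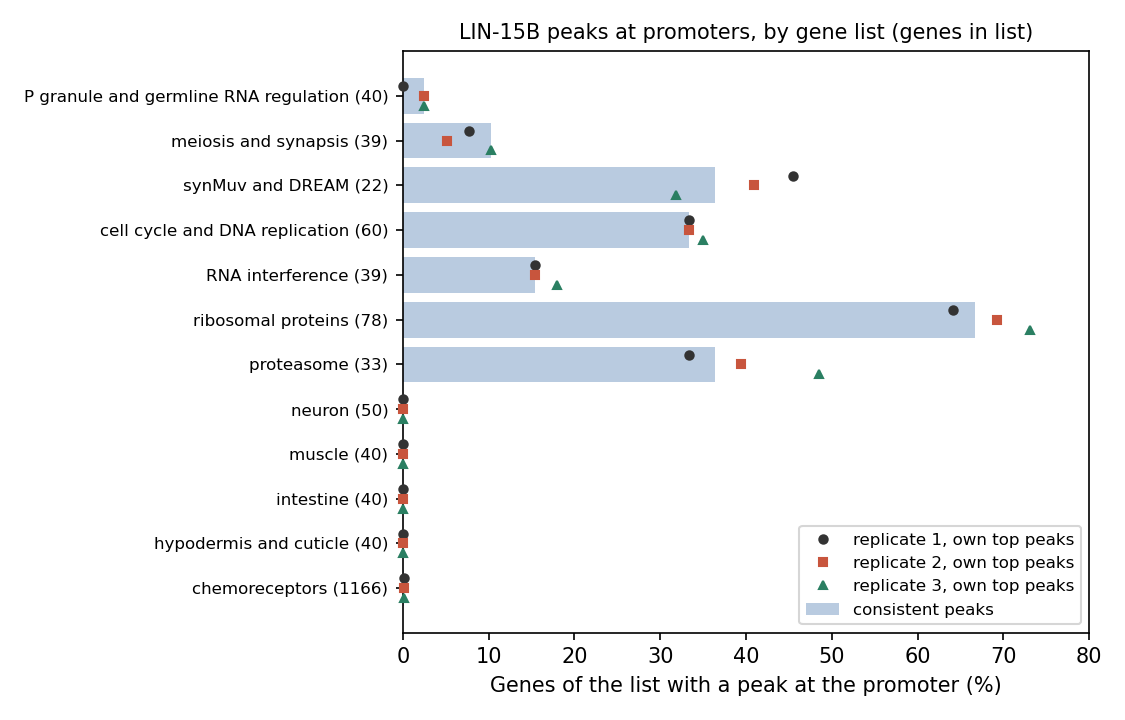
Share of genes with a peak at the promoter (horizontal axis, %) for the 12 lists, with the number of genes of each list in brackets. Bars show consistent peaks and points each replicate's own 926 strongest peaks; ribosomal proteins reach 66.7% and the 4 tissue lists stand at 0.

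Of the remaining fixed genes, lin-35, the retinoblastoma gene, and efl-1, an E2F gene, were bound. The promoter peak of lin-35 ranked 139, 180 and 102 in replicates 1, 2 and 3, and that of efl-1 ranked 133, 90 and 428. The peak of lin-35 was shared with another promoter. The E2F partner gene dpl-1 was not bound: its promoter had a listed peak of rank 8693 in replicate 2 and 1598 in replicate 3 and none in replicate 1. The cell cycle kinase gene cdk-1 was not bound either, with promoter peaks of rank 1360, 3420 and 957. Heterochromatin gene hpl-2, cyclin gene cye-1 and intestinal factor gene elt-2 had no listed promoter peak in any replicate. Histone methyltransferase gene met-2, Argonaute gene rde-1 and myosin gene unc-54 had listed promoter peaks only, none of them stronger than rank 5686.

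Bound genes were fewer on the X chromosome. Of 2731 X-linked genes 53 were bound (1.94%), against 995 of 17242 autosomal genes (5.77%), an odds ratio of 0.323 (Fisher's exact test, p = 1.38e-20). The replicates' own top peaks gave 1.97% ± 0.0423 for X and 5.73% ± 0.568 for autosomes (SD, n = 3). Chromosomes III and I had the highest shares, 9.39% and 8.30%, and chromosome V the lowest autosomal share, 3.02%. Consistent peaks lay at 3.72 per Mb on X and 10.4 per Mb on autosomes.

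Sequences under promoter peaks were rich in CpG. The ratio of observed to expected CpG was 1.49 ± 0.380 (SD over 756 windows) at bound promoters and 1.05 ± 0.468 (SD over 18925 windows) at others, with a permutation p of 1e-05, the smallest possible. GC content was 41.2% ± 6.44 against 34.1% ± 6.38 (permutation p = 1e-05). Much of the GC difference came with the choice of centre. With both sets centred 156 bp upstream of the annotated start, an alternative chosen after seeing the data, it was 2.00 percentage points instead of 7.08 for the nearest gene of each of the 756 peaks, and 1.53 for all 1048 bound genes (permutation p = 1e-05 for each). The CpG difference was 0.436 and 0.432 instead of 0.445. In windows of 50 bp either side of the summit, the GC difference was 13.6 percentage points.

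The E2F-like motif TTSSCGC stood in 26.9% of bound and 6.35% of other windows, an odds ratio of 5.42 (Fisher's exact test, adjusted p = 6.45e-65). Against windows of like GC content the odds ratio was 3.4. With both sets centred 156 bp upstream of the annotated start, it was 3.41 for the nearest gene of each peak (Fisher's exact test, adjusted p = 1.32e-28) and 3.06 for all bound genes (adjusted p = 1.69e-30 by Fisher's exact test). The motif itself holds a CG, and windows were not matched on the CpG ratio. Its excess is therefore not told apart from the CpG richness of bound promoters. The repeat GAGAGA was also more frequent at bound promoters, 27.4% against 15.2% (odds ratio 2.11, adjusted p = 8.69e-17 by Fisher's exact test). Its odds ratio was 1.49 and 1.37 with that common centre, for the nearest and for all bound genes, and 1.24 against windows of like GC content. The GATA-like motif WGATAR was less frequent, 21.7% against 41.5% (odds ratio 0.391, adjusted p = 4.11e-29 by Fisher's exact test), with an odds ratio of 0.660 and 0.686 at the common centre and 0.463 against windows of like GC content. The CHR-like motif TTYGAA stood in 57.0% and 55.8% (odds ratio 1.05, adjusted p = 0.526 by Fisher's exact test). Against windows of like GC content its odds ratio was 1.92 and passed the Mantel-Haenszel test. The E-box CACGTG did not differ past the threshold (odds ratio 1.18, adjusted p = 0.427 by Fisher's exact test). Of 2080 6-mers, 582 were more and 613 less frequent at bound promoters after adjustment, and each of the 20 with the smallest p held a CG. The first was GAGCGC, in 32.3% of bound and 3.15% of other windows, and in 19.7% of nearest-gene and 18.7% of all bound windows at the common centre.

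At the loci of the transgene, no promoter of lin-15B, lin-15A or unc-119 held a consistent peak. A consistent peak lay 939 bp upstream of lin-15B (WBGene00023497), with its summit at 15725184 of the X chromosome, outside the promoter as defined, and ranked 137, 128 and 99 in replicates 1, 2 and 3. Within 1000 bp of the lin-15B gene, from 15726123 to 15732025, replicates 1 and 2 had 11 peaks each and replicate 3 had 1. At lin-15A (15731968 to 15735365) the counts were 8, 5 and 0, and at unc-119 (chromosome III, 10902641 to 10908935) they were 6, 2 and 5.

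**Figure D3:**
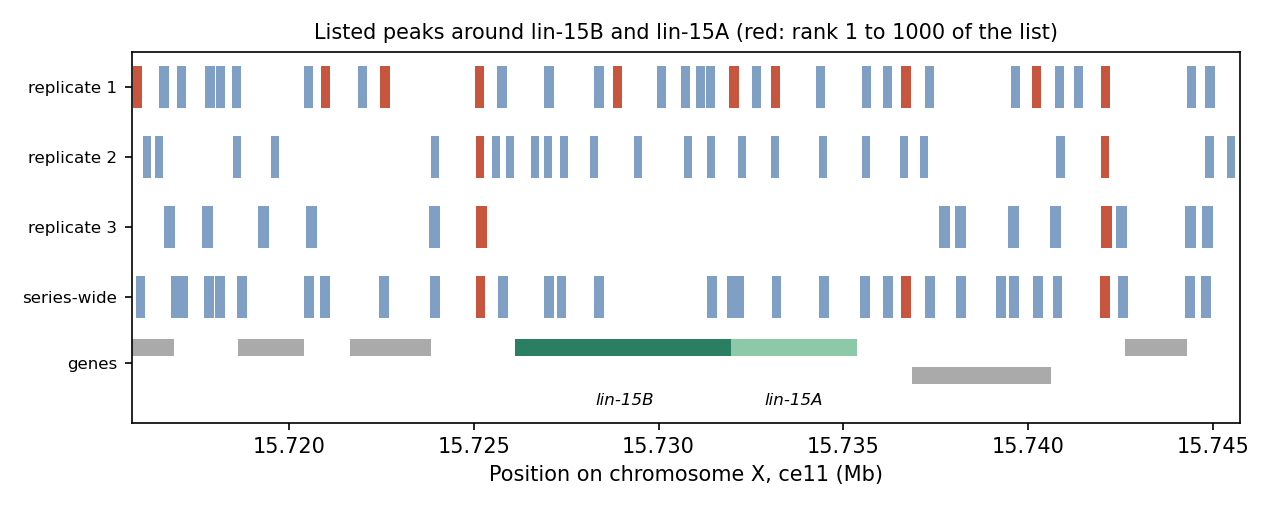
Listed peaks (boxes to scale) of each replicate and the series-wide list along chromosome X around lin-15B and lin-15A, with genes below (upper row forward strand, lower row reverse strand; horizontal axis, Mb on ce11). Red boxes rank 1 to 1000 in their list; replicates 1 and 2 have 11 peaks each within 1000 bp of lin-15B and replicate 3 has 1.

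The lists on ce10 and ce11 held the same number of peaks. Replicates 2 and 3 and the series-wide list had the same highest strength on both builds, and 29996, 30000 and 30000 of their sorted strengths lay within 1% of each other. In replicate 1 only 4352 did, its usual width was 250 bp on ce11 and 240 bp on ce10, and its highest strength 284 and 282. On the ce10 lists 936 peaks were consistent.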

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

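The alternatives without the lin-15 region, with 1 anchor per replicate peak and with both window sets centred 156 bp upstream of the annotated start were chosen after seeing the data. Of 321 recomputed values over 31 results, 307 kept their direction and side of the threshold or stayed within the limit set for counts and shares. The promoter share, the synMuv and DREAM, cell cycle, ribosomal, proteasome and chemoreceptor lists, the X chromosome, base composition and the E2F-like, GAGA and GATA-like motifs kept theirs under every alternative run for them, but not their size. Odds ratios without replicate 1 and with a pass in any pair were 5.65 and 6.50 for synMuv and DREAM, 17.4 and 18.9 for the proteasome, 14.1 and 14.3 for the cell cycle, 56.2 and 53.2 for ribosomal proteins, 0.0238 and 0.0226 for chemoreceptors and 1.13 and 1.07 for meiosis. The ribosomal odds ratio fell to 5.58 with 250 bp upstream to 100 bp downstream, where the chemoreceptors had 0, and to 16.6 with the nearest start only. Against genes with any listed promoter peak it was 17.6, with 7.34 for synMuv and DREAM, 4.27 for the cell cycle, 4.14 for the proteasome and 0.0243 for chemoreceptors. The P granule odds ratio, 0.463 in the main setting, was 0.844 without replicate 2. Bound genes numbered 701 with 250 bp upstream to 100 bp downstream, where the promoter share was 60.7%, 1839 without replicate 1 and 1929 with a pass in any pair. The GC difference ran from 1.53 percentage points with the common centre to 13.6 in windows of 50 bp either side, where the odds ratio was 7.08 for the E2F-like and 0.276 for the GATA-like motif. Consistent peaks numbered 2006 with a pass in any pair, and 1059 to 1829 with a replicate left out, the highest without replicate 1. The looser sets hold more peaks by construction. With a pass in any pair, the intestine list and the hypodermis and cuticle list, both still at an odds ratio of 0, passed the threshold (Fisher's exact test, adjusted p = 0.0444 each), since more genes were bound elsewhere. The RNA interference list lost its call with an odds ratio of 3.15 for the promoter of 250 bp upstream to 100 bp downstream, 2.13 for the nearest transcript start only and 2.35 against genes with any listed promoter peak, and the cause was not tested. Of results that had no call, the meiosis list turned to an odds ratio of 0.562 at an IDR of 0.01, the P granule list to 1.23 with 1000 bp upstream, the CHR-like motif to 0.900 in windows of 50 bp either side, and the E-box to 0.970 with GC matching and, with the common centre, 0.693 for all bound genes and 0.832 for the nearest gene of each peak; none of these passed the threshold, and the cause was not tested. The CHR-like motif passed it at 1.92 with GC matching, for which the cause was not tested. Depth is unknown, so a gene without a consistent peak is not shown to be unbound.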

Other observations

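Families of genes by name were examined after the data were seen, with members of the 12 lists left out. Of 97 families with 15 or more members, 8 were bound above other genes and 3 below after adjustment (Fisher's exact test). Nuclear pore genes (npp) had 10 of 26 bound, with npp-3 and npp-13 ahead (Fisher's exact test, adjusted p = 3.61e-05), DnaJ chaperone genes (dnj) 10 of 29 (adjusted p = 5.9e-05) and translation initiation genes (eif) 7 of 16 (adjusted p = 0.000261). Cyclophilin (cyn, 6 of 16), cytochrome oxidase (cox, 5 of 15), vesicle sorting (vps, 7 of 31), mitochondrial ribosome (mrpl, 8 of 41) and heat shock (hsp, 5 of 22) genes followed, with adjusted p from 0.00203 to 0.0433. The nuclear hormone receptors (nhr) had 1 of 267, nhr-47, the C-type lectins (clec) 2 of 239, clec-87 and clec-126, and the F-box family fbxa 0 of 170 (adjusted p = 0.00048, 0.00833 and 0.00299 by Fisher's exact test).

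Peaks often lay between diverging genes or where promoters overlap: 293 of 756 promoter peaks (38.8%) were in the promoters of more than 1 gene, and such sequence makes up 5.89% of all promoter sequence. Small RNA genes also had summits within 100 bp, 8 of 129 snRNA genes, 9 of 346 snoRNA genes and 7 of 612 tRNA genes. Circular shifts tested the share of consistent peaks near such genes. It was 0.972% for snRNA, 1.08% for snoRNA and 0.648% for tRNA genes, against 0.0419%, 0.129% and 0.135% for shifted peaks. By these shifts, the adjusted permutation p was 2e-05, 2e-05 and 0.00257. The shifts covered whole chromosomes, so nearness of these genes to protein-coding promoters was not accounted for. None of 20 rRNA genes had a summit within 100 bp (adjusted permutation p = 1), and shifted peaks gave 0.0151%, too few to show a lack. These tests were chosen after the data were seen.

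Of the tests that follow, those of the mapping property, of the labels of replicate 3, of the chances for replicates 2 and 3, of transcription and of the highest GC window were chosen after the result was seen. Peaks were crowded around lin-15B and lin-15A in replicates 1 and 2. Within 15 kb of the middle of the genes, replicate 1 had 34 peaks, replicate 2 had 25 and replicate 3 had 14, against a median of 9 per window. Most of them scored low: 4, 8 and 4 in replicates 1, 2 and 3 had a q score of 2 or more. A mapping property of the reference sequence stays open: 14.8% of windows were as dense in replicate 3, but that is 1 library, labelled with another fragmentation, and its low count is part of the pattern. Extra copies of inserted lin-15 DNA are a candidate explanation that the promoter share cannot decide. Outside consistent peaks, 8 of the region's 55 peaks in replicates 1 and 2 were in promoters. That is 14.5% (95% Wilson interval 7.56 to 26.2), as for the sequence of the region (14%). The 926 weakest peaks of each list had a mean share of 17.5%, so background gives a low share anywhere. Other sources of raised background would give the same. The interval treats all 55 peaks as independent, though some of the 2 replicates lie at the same place. Why replicate 3 differs is confounded with its stock source and fragmentation, and no biological explanation was tested.

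Pairs with replicate 1 had fewer reproducible peaks. The labels set replicate 3 apart, and replicates 2 and 3 shared 1.73 times as many peaks as replicates 1 and 2, but these counts define the pattern and exclude nothing. Of the 1829 peaks of replicates 2 and 3, the 970 among the top 2000 of replicate 1 outranked the other 859 with a chance of 0.850, but the same chance was 0.852 when replicate 2 was searched and 0.847 when replicate 3 was, so it does not single out replicate 1. The share found was lower in replicate 1, 53.0% against 87.9% in replicate 2 and 85.3% in replicate 3, which is the pattern itself and does not tell its reasons apart. Weaker enrichment and lower depth of replicate 1 and the labelled difference of replicate 3 stay open, and no biological explanation was tested.

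The 5 lists bound above other genes might have followed GC-rich promoters. Promoters were first pooled by GC content in the window centred 156 bp upstream of the annotated start. The odds ratios were then 11.6 for synMuv and DREAM, 8.59 for the cell cycle and 3.48 for RNA interference. They were 42.9 for ribosomal proteins and 10.9 for the proteasome. By the highest GC window of each promoter they were, in the same order, 9.66, 8.30, 3.17, 28.7 and 9.21. All 95% intervals stayed above 1. The first window can miss the bound site. In it, ribosomal promoters held 31.5% GC against 34.2% in others, but 48.4% against 43.7% by the highest window. The lists were not pooled by CpG ratio, so CpG content stays open. Of the listed muscle, intestine and hypodermis genes together, 0 of 120 were bound (Fisher's exact test, p = 0.00306), and 0 to 3 with a replicate left out, but the lists were pooled after each was seen at 0, none passed alone, and their transcription was not measured. High transcription, in any tissue or in all cells at once, and binding that many factors share at open promoters stay open, since neither expression nor a control sample was analysed here. No biological explanation was tested.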
